A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

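H3K9me3 was measured in 4 groups of Schizosaccharomyces pombe cells with 1 array each: wt ON, wt OFF, clr3-CDx2 ON and clr3-CDx2 OFF. Per the labels, cells were grown at 32 °C for 20 generations without thiamine and for 5 generations in 850 µg/ml 5-fluoroorotic acid, and part of the culture was fixed in 3% paraformaldehyde as ON cells. The rest was grown for 14 generations with 5 µg/ml thiamine and 2.5 µg/ml tetracycline and fixed as OFF cells. Chromatin of about 1000 bp was precipitated with 2 µg of an H3K9me3 antibody, and precipitated DNA (Cy5) and whole-cell extract DNA (Cy3, the input) were amplified and hybridised together to a custom array of 60-mers spaced 300 bp apart. The labels do not say what clr3-CDx2 is, and nothing was assumed beyond its name. All 4 arrays lay on 1 slide and were read in 1 scan. Batches of culture, precipitation, amplification and labelling are not recorded, and OFF cells were fixed after ON cells, so the time of harvest cannot be told apart from the switch. ON cells were fixed after growth in 5-fluoroorotic acid, which is not named for the 14 generations that followed. An end of that treatment cannot be told apart from the switch either.

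The scanner files were made by the authors with Agilent Feature Extraction 12.0.3.1. Per the file headers, they hold spot and background intensity in each channel, a dye-normalised processed signal in each channel, a log10 ratio of the processed signals, and marks for saturated, non-uniform and dim spots. The deposited series matrix holds a log2 ratio of ChIP over input: its values equalled the log2 ratio of the processed signals to within 0.01 on each tile of the 4 arrays, and 1 tile per array departed from the log10 ratio once both were on the same scale. Scale, direction and centring of the matrix were found from these values. Its columns are not centred, with medians of 0.234 in wt ON, 0.173 in wt OFF, 0.296 in clr3-CDx2 ON and 0.185 in clr3-CDx2 OFF. The dye normalisation in the scanner files is linear, with no intensity-dependent part.

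The value analysed was the log2 ratio of processed ChIP to processed input signal, less the median tile of the array, with no loess or quantile step. The mode of the ratios lay above the median by 0.241 in wt ON, 0.0616 in wt OFF, 0.244 in clr3-CDx2 ON and 0.0554 in clr3-CDx2 OFF. Of 41551 tiles, 18457 are on chromosome I, 14836 on II and 7958 on III, 110 on a mating-type contig, 61 on the mitochondrial genome and 129 on subtelomeric clones, and 1417 control spots were left out. Spots marked non-uniform were left out on the array where they were marked, 261 in wt ON, 190 in wt OFF, 194 in clr3-CDx2 ON and 578 in clr3-CDx2 OFF. No tile was saturated. The median signal was 425 to 486 times background in the input channel and 137 to 171 times in the ChIP channel, and the number of arrays limits the precision of each difference.

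Tiles were placed on the reference genome by the name each carries, and each chromosome arm was shifted by the offset that best matched input signal to GC content, from -1750 to 4500 bp. The correlation was 0.22 to 0.28 at the chosen offsets and at most 0.08 further than 1 kb away, and positions printed are those of the array. Tiles counted as repeated were the 1276 tiles named as repeated on the array or placed on stretches found more than once by 31-mers. Pericentromeres were the longest gene-free interval of each chromosome, subtelomeres the 50 kb at each end of chromosomes I and II, and the ends of chromosome III the outer 25 kb. The mating-type region was the whole of the separate contig on the array. The plan had named the stretch between mat2 and mat3, so this is a departure from it. A domain was a run of at least 5 tiles at 1 or more on the log2 scale after a running median of 3 tiles, with a gap of 1 tile allowed. The ectopic domain was the longest domain outside the fixed regions found in both ON arrays, and its core the part common to both. It was chosen on ON arrays, which favours a fall in OFF. The same domain was therefore also taken over its extent in wt ON alone and in clr3-CDx2 ON alone. Both extents come from the pair found on both ON arrays, and that in clr3-CDx2 ON equals the core, so it is no separate check.

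A region's difference is the median over tiles of the difference between arrays. A gene's value is the median over at least 2 tiles in it, and its difference is that of the medians. A gene was counted as higher or lower when it moved by at least 1 on the log2 scale and reached at least 1 on an array compared. Named genes are the 10 largest rises and falls in each comparison among those counted, up to 15 genes of the ectopic domain in order of ON enrichment, and the members of 6 lists, in which mcp5 is annotated as num1. Windows were drawn outside the fixed regions and the ectopic domain, from stretches without marked tiles and of at most 160 tiles, and random lists were matched on input signal. The comparisons, regions, lists and naming rule were set before the data were examined, apart from the extent of the mating-type region. The genes of the right flank, which follow from the extent of the domain in wt ON, were chosen after their values were seen.

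Alternatives were normexp background correction with an offset of 50 (limma 3.58.1 in R 4.3.3), no background subtraction, the series matrix values, centring on the mode, and scaling to pericentromeres. That scaling multiplied the log2 ratios of each array so that the median over all 360 pericentromeric tiles, marked ones included, was the same. Marked tiles were then left out again, so pericentromere medians given under the scaling still differ between arrays. Further ones left out tiles dim in the input channel or repeated tiles, used the ChIP channel alone, moved domain edges to 1.5-fold or 3-fold, required 10 tiles, dropped the running median, or took gene means. Keeping the marked tiles and shifting tiles by 300 bp were chosen after seeing the data. The files hold median rather than mean spot signals, so normexp and the unsubtracted ratio used medians, a departure from the plan. Other work used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. The procedure was tested on simulated data: 40 of 40 planted domains were found with edges exact to the tile and 0 elsewhere, a planted ectopic change of 3 was measured as -3.04 for a loss, and 200 of 200 genes planted at 2 on the log2 scale were called. A further 13 unplanted genes were called, each sharing tiles with a planted one. Simulated tiles varied less than the real tiles outside the regions, whose SD was 0.87 to 1.00 between arrays. Domains were planted at 3, whereas real ones outside the fixed regions had medians of 1.28 to 1.36. The simulation therefore checks the code and does not show how exact or how often false the real domains are. Mitochondrial tiles and the subtelomeric clones, whose place on the chromosomes the array names do not give, were left out of the comparisons.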

Results

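H3K9me3 was mapped by ChIP on a genome tiling array in fission yeast cells carrying tetR-clr4, a fusion of the Tet repressor to the H3K9 methyltransferase Clr4. Wild-type (wt) and clr3-CDx2 cells were sampled with tetR-clr4 ON, and again 14 generations after thiamine and tetracycline were added (OFF). The clr3 gene, which encodes a histone deacetylase, read 0.55 (log2 ChIP over input) in wt ON and 0.65 in wt OFF, against -1.39 in clr3-CDx2 ON and -1.32 in clr3-CDx2 OFF. Between genotypes its ChIP signal alone differed by -1.68 in ON and -1.64 in OFF cells and its input signal by 0.28 and 0.33, while the 20 tiles beside the gene differed by -0.23 and -0.34 in ratio. The endogenous clr4 gene read 1.14 in wt ON, 1.36 in wt OFF, 1.18 in clr3-CDx2 ON and 1.44 in clr3-CDx2 OFF. Each group had 1 array, so no difference could be set against a spread between replicates and no p-value was computed. Regions were instead ranked among 10000 random windows of the genome, and gene lists among 10000 random lists of genes with similar input signal. The windows lie outside the fixed regions and the ectopic domain. A rank among them therefore does not show how far enriched regions vary from array to array.

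Pericentromeres, the silent mating-type contig and the subtelomeres of chromosome I carried H3K9me3 on each of the 4 arrays. Over the 360 tiles of the pericentromeres of chromosomes I, II and III, the median enrichment was 1.53 in wt ON, 2.50 in wt OFF, 2.11 in clr3-CDx2 ON and 2.35 in clr3-CDx2 OFF, above each of the 10000 random windows, although the pericentromere of chromosome II taken alone read 0.10 in clr3-CDx2 ON, at percentile 60.5. Each pericentromere was taken as the longest gene-free interval, and repeated and unique tiles within it read far apart. The 278 repeated tiles had medians of 3.96, 4.98, 3.73 and 4.36, and without them the medians were 0.28, 1.23, -0.41 and 1.06, in the same order. At chromosome II in clr3-CDx2 ON the 63 repeated tiles read 3.65 and the 45 unique tiles -2.27. The 0.10 given there is the median of this mix and does not show that the mark was absent. The first set of medians leaves out spots that the scanner software marked as non-uniform, which on at least 1 array were 32.8% of pericentromeric tiles against 2.37% of all tiles, and with those spots kept they were 3.56, 4.50, 2.76 and 4.36 in the same order. The silent mating-type contig, 110 tiles, read 1.06 in wt ON, 2.05 in wt OFF, 1.08 in clr3-CDx2 ON and 1.67 in clr3-CDx2 OFF, and with marked spots kept 3.07, 4.29, 2.08 and 3.54. Its signal was uneven: in wt ON the stretch starting at 9000 read -0.11 and that at 24000 read 4.46. The medians therefore depend on how many tiles of each kind are used. Subtelomere I left read 1.46, 2.21, 2.24 and 3.82 and subtelomere I right 0.93, 1.78, 2.90 and 4.55, at percentile 99.92 or higher. Over their 50 kb the subtelomeres of chromosome II had medians inside the range of the random windows in ON cells, at 0.28 left and -0.02 right in wt ON and 0.24 and -0.22 in clr3-CDx2 ON (percentiles 28.6 to 78.0), and read 0.68 and 0.66 in wt OFF and 0.91 and 0.42 in clr3-CDx2 OFF (88.6 to 99.2). Shorter domains lay within them in ON cells, covering 9.60 kb on each side in wt ON, and 15.6 kb on the left and 12 kb on the right in clr3-CDx2 ON, and the longest of each had medians of 1.53 and 1.44 in wt ON and 2.13 and 2.37 in clr3-CDx2 ON. Left and right, their repeated tiles read 1.04 and 1.05 in wt ON and 1.85 and 2.05 in clr3-CDx2 ON. Their unique tiles read 0.03 and -0.24 in wt ON and -0.01 and -0.55 in clr3-CDx2 ON. Signal on repeated tiles cannot be assigned to chromosome II alone. The subtelomeric helicase gene tlh1 read 4.80, 5.59, 4.09 and 5.66, and tlh2 had no tiles to measure it. The 10 measured Tf2 retrotransposons of 13 had medians of 2.09, 2.22, 2.20 and 2.36, above each of the random lists, while 11 euchromatic controls such as act1, adh1 and pgk1 had medians of -1.81, -1.43, -2.13 and -1.32, below each of them. The loci of 20 heterochromatin factors, among them clr1, rik1, mit1 and dcr1, had medians of 0.88, 0.88, 0.92 and 0.85, at percentile 99.85 or higher of the random lists. From ON to OFF they changed by 0.03 in wt and -0.02 in clr3-CDx2, and the Tf2 elements by 0.10 and 0.04. Outside the regions the ratio rose with GC content on each array (Spearman rho 0.18 to 0.24), on which the lists were not matched. Whether these list levels reflect H3K9me3 or a background that varies along the genome was not tested.

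Outside these regions, runs of at least 5 tiles enriched 2-fold or more were found at 391 places in wt ON, 406 in wt OFF, 440 in clr3-CDx2 ON and 509 in clr3-CDx2 OFF. Centring on the mode gave 202 in wt ON and 253 in clr3-CDx2 ON, and the uncentred deposited ratios gave 601 and 731. Most of the runs first given were short and weak, with a median length of 2.40 kb, or 2.70 kb in clr3-CDx2 ON, and a median enrichment from 1.28 to 1.36. The longest found in both ON arrays lay on the left arm of chromosome III, at array positions 99300 to 126300, and spanned 27.3 kb and 90 tiles. The 8 genes analysed within it are ura4, a selectable marker gene of uracil synthesis, pmp20, mug135, the DNA repair genes rhp7 and rhp16, alg11, SPCC330.03c and SPCC330.07c. The core shared by both ON arrays had a median of 3.22 in wt ON (9.32-fold), 0.13 in wt OFF, 2.67 in clr3-CDx2 ON (6.36-fold) and 2.98 in clr3-CDx2 OFF (7.91-fold). In wt ON the domain ran on to position 147000 and covered 48.6 kb, and in wt OFF a run of 5 tiles was left. In clr3-CDx2 the unbroken run covered 27.3 kb both in ON and in OFF cells, but signal went on to its right. In clr3-CDx2 ON, stretches starting at 126000, 128000 and 130000 read 0.87, 0.71 and 0.88, just under the cut of 1. Further right, the stretch at 132000 read 1.75 in clr3-CDx2 ON and 1.79 in OFF, and that at 138000 read 2.73 and 0.27. The shorter length in clr3-CDx2 thus depends on the cut. The right flank that wt ON added, 69 tiles, had medians of 1.78 in wt ON, -0.09 in wt OFF, 1.05 in clr3-CDx2 ON and 0.84 in clr3-CDx2 OFF.

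**Figure D1:**
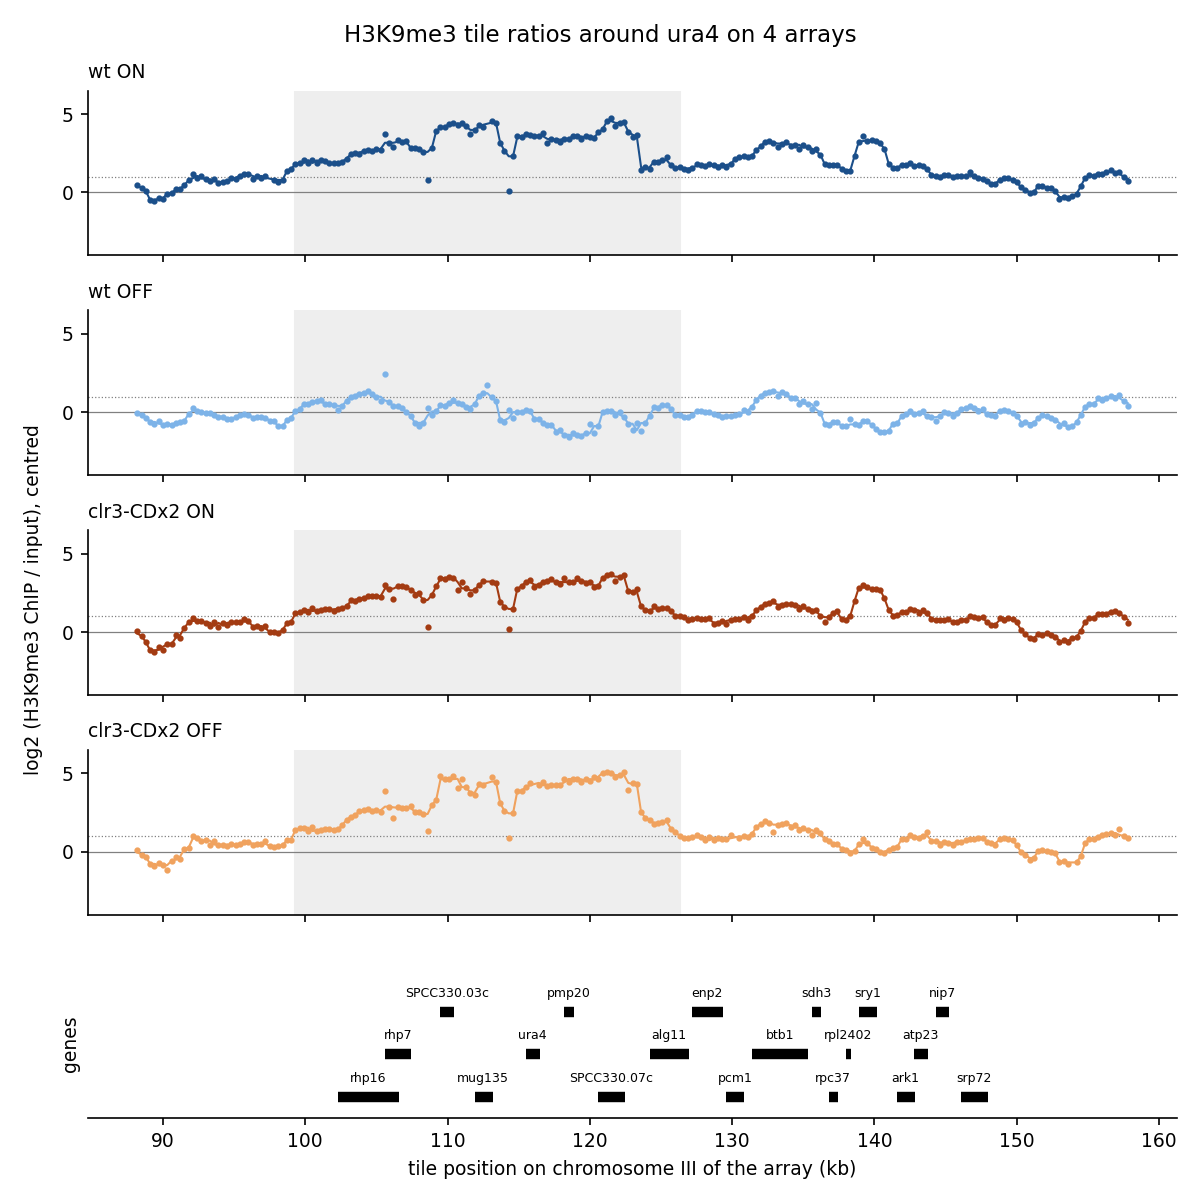
H3K9me3 enrichment (log2 ChIP over input, vertical axis) along the left arm of chromosome III (array position in kb, horizontal axis), with 1 panel per array, tiles as points, their running median over 3 tiles as a line, the core shaded and genes drawn below. Over the core the median is 3.22 in wt ON, 0.13 in wt OFF, 2.67 in clr3-CDx2 ON and 2.98 in clr3-CDx2 OFF.

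In wt cells the ectopic domain was lost after the switch. Across the core, H3K9me3 fell by 3.29 on the log2 scale (9.81-fold lower), below each of the random windows, and 98.9% of its tiles were lower in OFF. Each of these 8 core genes was at least 2-fold lower: pmp20 changed by -4.85 (28.8-fold lower), SPCC330.07c by -4.44, ura4 by -3.81 (14.0-fold lower), SPCC330.03c by -3.75, mug135 by -3.22 and rhp7 by -2.87. In the right flank 10 of 11 genes were at least 2-fold lower, led by sry1, a serine racemase gene, at -4.09, sdh3 at -2.45 and rpc37 at -2.40. A further fall was at ade6, the adenine marker gene, outside the domain on the same chromosome, at -3.04. Among genes that also reached 2-fold enrichment on at least 1 array compared, called enriched genes from here on, 26 of the 4945 measured protein-coding genes were lower by at least 2-fold and 9 were higher.

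Pericentromeres moved the other way in wt, rising by 0.73 (1.66-fold), and so did the mating-type contig (0.76), the subtelomeres of chromosome I (0.72 left, 0.83 right) and those of chromosome II (0.46 left, 0.74 right). The ends of chromosome III were lower in OFF and changed by -0.69 on the left, at percentile 0.03, and by -0.18 on the right, at percentile 2.60, the latter 0.0046 when arrays were centred on the mode. All 59 tiles of the left end are repeated ones. The 9 enriched genes that rose were bsu1, a vitamin B6 transporter gene, at 2.53, SPCC162.02c at 1.85, SPAC750.07c at 1.71, SPAC750.08c at 1.25, mae1 at 1.14, mae2 at 1.08, SPBC23G7.14 at 1.05, SPBCPT2R1.01c at 1.03 and SPAC977.14c at 1.02. Of 13 facultative islands and meiotic genes, 11 were lower, with a median of -0.20, below each of the random lists, and -0.02 when arrays were centred on the mode of their ratios. As a list they were not enriched on any array. Their median levels were 0.23 in wt ON, -0.09 in wt OFF, 0.23 in clr3-CDx2 ON and -0.07 in clr3-CDx2 OFF. These lay at percentiles 59.3, 19.6, 52.1 and 21.1 of the random lists. The largest falls in that list were at mcp7 (-0.62) and num1 (-0.62). The euchromatic controls had a median of 0.05, at percentile 71.0, and -0.01 with the uncentred deposited ratios. tlh1 differed by 0.79, and by -0.39 when arrays were scaled to equal pericentromeric signal. The ectopic fall was -2.14 on the ChIP channel alone. The 9 enriched genes that were higher became 22 with normexp background correction, 19 when arrays were centred on the mode, 5 without repeated tiles, 3 on the ChIP channel alone and 2 under the pericentromeric scaling.

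In clr3-CDx2 cells the ectopic domain was kept after the same switch. The core was 0.89 higher in OFF than in ON, above each of the random windows, with 89.9% of its tiles higher, but -0.55 when arrays were scaled to equal pericentromeric signal. The pericentromeres rose further without that scaling, by 1.42, so the rank among windows does not set the core apart from other enriched regions. Of the 8 core genes analysed 7 were higher, 5 of them by at least 2-fold, and ura4 went from 3.11 to 4.24, pmp20 from 3.18 to 4.64, SPCC330.07c from 3.53 to 5.03 and mug135 from 3.11 to 4.27, while rhp7 went from 2.86 to 2.83. The right flank differed by -0.13, where sry1 alone of 11 genes fell 2-fold or more, from 2.83 to 0.49 (-2.35). ade6 rose from 2.36 to 4.04.

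Pericentromeres, mating-type contig and subtelomeres also rose in clr3-CDx2, by 1.42 (2.68-fold) at the pericentromeres, 1.18 at the mating-type contig, 1.68 at subtelomere I right, 0.82 at subtelomere II left and 0.77 at subtelomere II right, with subtelomere I left 2.82-fold higher. These regions rose together in both genotypes. With 1 array per group, such a shared rise cannot be told apart from a difference in precipitation or labelling between arrays. The ends of chromosome III were lower and changed by -0.87 on the left, below each of the random windows, and by -0.22 on the right, at percentile 0.84, the latter 0.24 under the pericentromeric scaling. At least 2-fold higher were 45 enriched genes, of which 15 lay in subtelomere I right, 8 in subtelomere I left, 4 in each subtelomere of chromosome II and 5 in the ectopic core. These 45 were led by bsu1 at 2.88, SPAC57A7.05 at 2.43, SPCC162.02c at 2.36, the silent mating-type gene mat3-Mc at 2.01, SPAC750.07c at 1.94, SPBCPT2R1.01c at 1.84, SPAC186.07c, SPAC750.06c and SPAC750.08c at 1.77 each and ftm5 at 1.76. Lower were 10 enriched genes: after sry1 came coq6, of ubiquinone synthesis, at -2.21, bop1 at -1.72, SPAP32A8.02 at -1.42, msn5 at -1.35, rsc58 at -1.30, pre1 at -1.26, pmd1 at -1.14, ash2 at -1.12 and num1 at -1.10. The facultative islands and meiotic genes had a median of -0.33, below each of the random lists (-0.15 when arrays were centred on the mode), with mei4, a meiotic transcription factor gene, at -0.97 and ssm4 at -0.76. The euchromatic controls had a median of 0.53, above each of the random lists, and tlh1 differed by 1.57, or by -0.70 under the pericentromeric scaling. That scaling makes the pericentromere median with marked tiles kept the same on each array, and so cannot show its change. With marked tiles left out, the scaled medians still differed, at 2.11 in wt OFF and 2.91 in clr3-CDx2 ON. Under that scaling subtelomere I right differed by 0.01, and 4 rather than 45 enriched genes were higher and 28 rather than 10 lower. Without repeated tiles 23 were higher, on the ChIP channel alone 8 were higher and 3 lower, and with centring on the mode 6 were lower. Without scaling, the difference over the wt ON extent of the ectopic domain was 0.16.

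**Figure D2:**
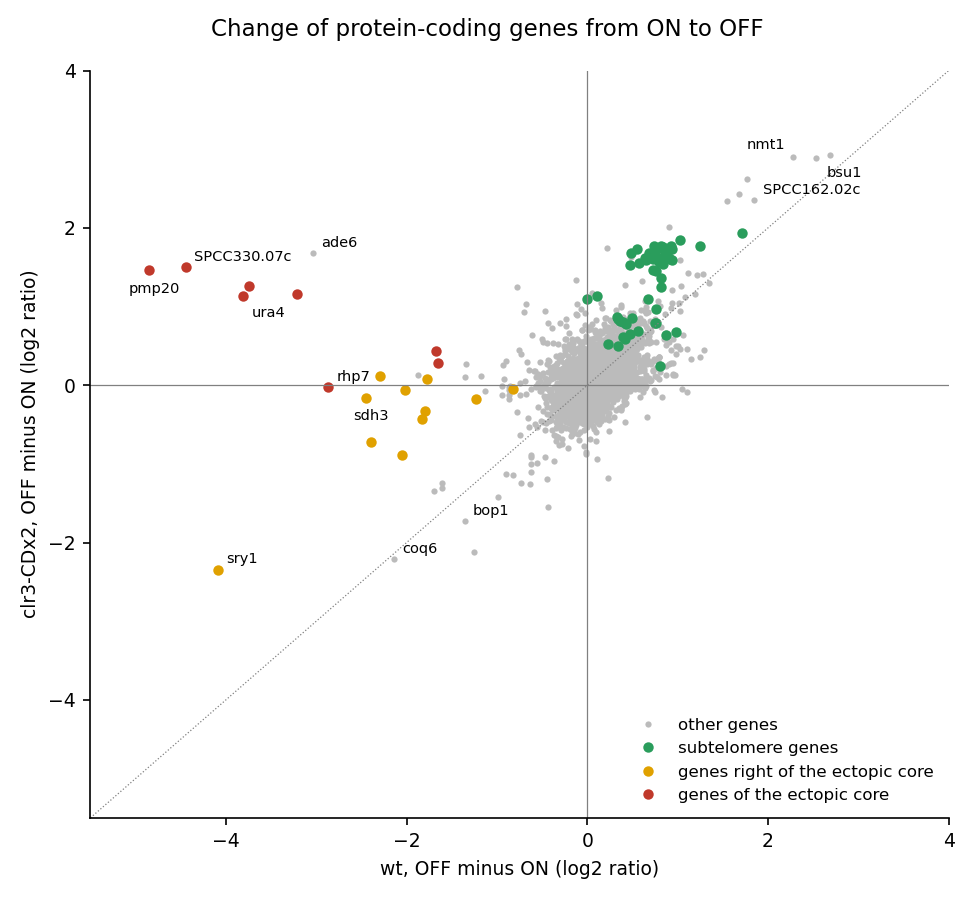
Each point is a protein-coding gene, placed by its OFF minus ON difference in log2 enrichment in wt (horizontal axis) and in clr3-CDx2 (vertical axis), with core, right flank and subtelomere genes coloured and equal change dotted. ura4 lies at -3.81 and 1.13, and ade6 at -3.04 and 1.68.

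Before the switch, with tetR-clr4 ON, clr3-CDx2 read higher than wt at the right end of chromosome I and lower at the pericentromeres. The mating-type contig and tlh1 read lower together with the pericentromeres. With 1 array per group, such a shared fall cannot be told apart from a difference in precipitation or labelling between arrays. Subtelomere I right, 159 tiles, was higher by 1.97 (3.92-fold), above each of the random windows, and domains there covered 52.5 kb in clr3-CDx2 ON, as 1 domain, against 24.3 kb in wt ON, in 4 domains of which the longest spanned 16.2 kb. Of the 18 enriched genes at least 2-fold higher, 11 lay there: SPAC186.06 was higher by 2.66, SPAC186.07c by 2.58, the pyruvate decarboxylase gene pdc102 by 2.42, SPAC186.04c by 2.37, SPAC186.08c by 2.31, gdt1 by 2.29, SPAC750.01 by 2.05, SPAC186.03 by 1.73 and SPAC186.02c by 1.68, with SPAC977.14c, outside that region, at 1.89. The pericentromeres differed by -0.78 and the mating-type contig by -0.54 over tiles used on both arrays, although their medians given above, taken over different tiles on each array, were higher in clr3-CDx2 ON. Over the 242 pericentromeric tiles unmarked on all 4 arrays the medians were 0.92 in wt ON and 0.08 in clr3-CDx2 ON. Subtelomere I left differed by 0.12, subtelomere II left by 0.03 and subtelomere II right by -0.18. The left end of chromosome III differed by -1.63, below each of the random windows, and its right end by -0.32. The 59 tiles of the left end are all repeated. In the ectopic core the difference was -0.55, and 0.05 under the pericentromeric scaling. The 6 enriched genes at least 2-fold lower in clr3-CDx2 were pcm1 (-1.33), btb1 (-1.32), sdh3 (-1.29), ade6 (-1.28), mug135 (-1.14) and mat3-Mc (-1.13), and clr3 itself, below that enrichment, differed by -1.94. The facultative islands and meiotic genes had a median of 0.21, at percentile 99.94, the euchromatic controls -0.24, at percentile 0.12, and tlh1 differed by -0.71, or by 0.51 under the pericentromeric scaling. Under that scaling 34 rather than 18 enriched genes were higher and 1 rather than 6 lower, without repeated tiles 10 were higher, and on the ChIP channel alone 10 were higher and 0 lower.

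**Figure D3:**
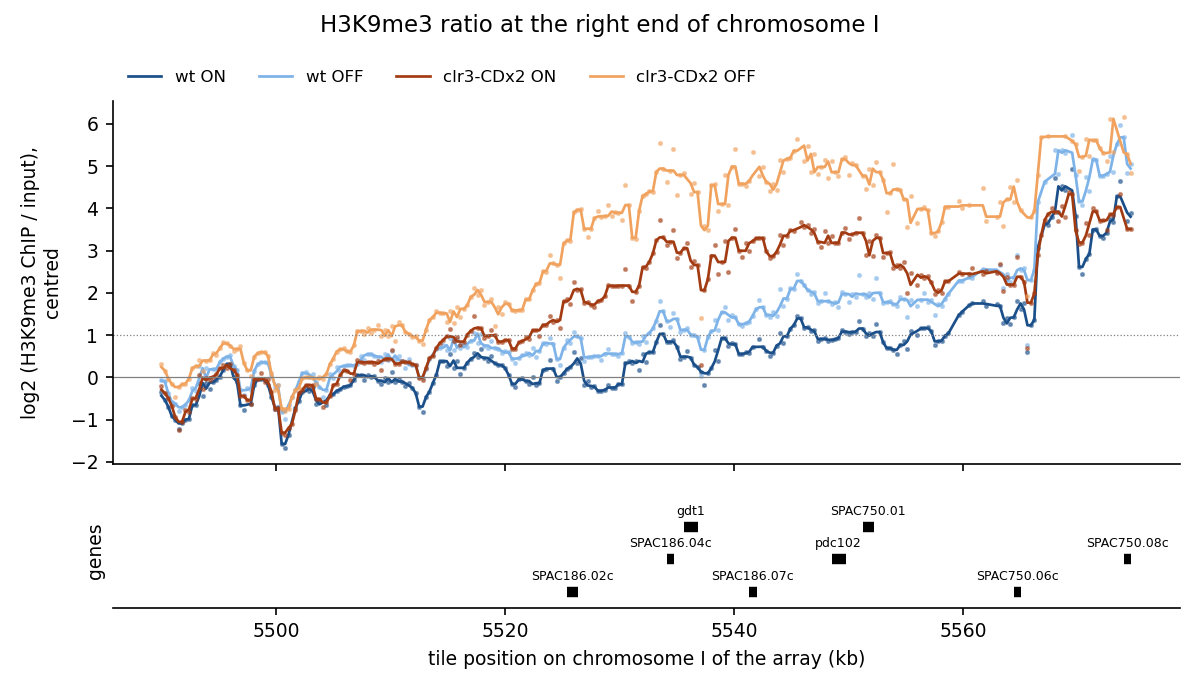
H3K9me3 enrichment (log2 ChIP over input, vertical axis) at the right end of chromosome I (array position in kb, horizontal axis), with tiles as points, their running median over 3 tiles as 1 line per array and genes drawn below. The median over the last 50 kb is 0.93 in wt ON, 1.78 in wt OFF, 2.90 in clr3-CDx2 ON and 4.55 in clr3-CDx2 OFF.

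After the switch the genotypes differed in the ectopic domain and again at the right end of chromosome I. The ectopic core was higher in clr3-CDx2 OFF than in wt OFF by 3.23 (9.40-fold), in 100% of its tiles, with pmp20 at 6.07 (67.2-fold), SPCC330.07c at 5.03, ura4 at 4.42 (21.4-fold) and SPCC330.03c at 4.20. Subtelomere I right was higher by 2.92 (7.58-fold), with SPAC186.04c at 3.56, SPAC186.07c at 3.54, gdt1 at 3.47, SPAC186.06 at 3.45 and pdc102 at 3.34, and ade6 was higher by 3.44. Domains there covered 61.8 kb in clr3-CDx2 OFF, as 1 domain, against 40.8 kb in wt OFF, in 2 domains of which the longest spanned 36.9 kb. Of 40 enriched genes at least 2-fold higher, 13 lay in subtelomere I right, 8 in the ectopic core and 6 in subtelomere I left, which was 0.69 higher. The 40 became 24 without repeated tiles and 23 on the ChIP channel alone. No enriched gene was lower by 2-fold, although 1 was with normexp and 1 on the ChIP channel alone. The pericentromeres differed by -0.14, at percentile 3.38, the mating-type contig by -0.20, subtelomere II left by 0.33, subtelomere II right by -0.20 and the ends of chromosome III by -1.78 on the left and -0.47 on the right, the latter 0.0010 on the ChIP channel alone. The facultative islands and meiotic genes had a median of 0.02, or -0.01 with normexp, and the euchromatic controls -0.01, both inside the range of the random lists at percentiles 39.2 and 38.1. tlh1 differed by 0.07, or by -0.24 with normexp. On the wt ON extent of the ectopic domain the difference was 1.29.

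**Figure D4:**
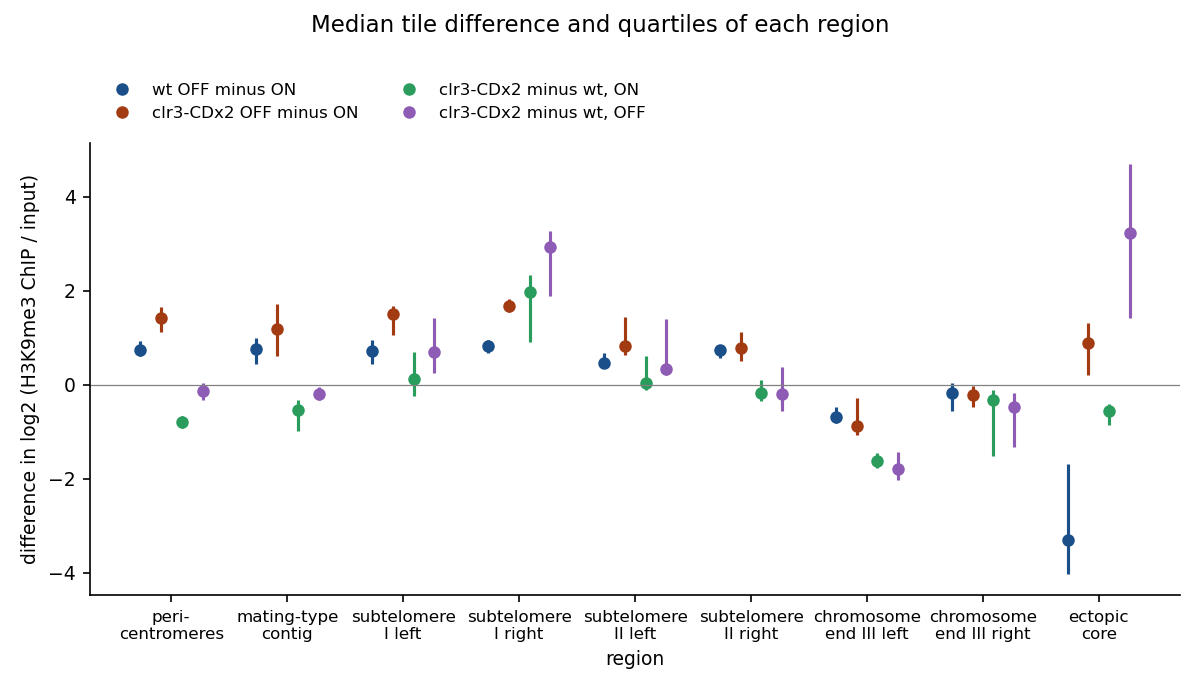
Points are the median tile difference in log2 enrichment (vertical axis) of each region (horizontal axis) and lines its quartiles, with 1 colour per comparison. The ectopic core stands at -3.29 for wt OFF minus ON and 0.89 for clr3-CDx2 OFF minus ON (-0.55 when arrays are scaled to equal pericentromeric signal).

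After the switch the ectopic core changed in opposite directions in wt and clr3-CDx2, at -3.29 and 0.89, except under the pericentromeric scaling, where it was -0.55 in clr3-CDx2. The difference of differences, clr3-CDx2 OFF minus ON less wt OFF minus ON, was 3.69 (12.9-fold) in the core, above each of the random windows and positive in 100% of its tiles, and 1.78 in the right flank. By gene it was 6.31 at pmp20, 5.94 at SPCC330.07c, 5.00 at SPCC330.03c, 4.94 at ura4, 4.72 at ade6, 4.38 at mug135, 2.85 at rhp7, 2.41 at pcm1, 2.29 at sdh3 and 2.11 at rhp16. Among enriched genes, 31 were at 1 or more on the log2 scale, 10 of them flank genes, and 0 were at -1 or less. Under the pericentromeric scaling these counts were 18 and 4, and with normexp 1 was at -1 or less. In the constitutive regions it was 0.66 at the pericentromeres, 0.26 at the mating-type contig, 0.41 at subtelomere II left and 0.13 at subtelomere II right, the last -0.04 without repeated tiles. At subtelomere I it was 0.65 on the left and 0.83 on the right, but -0.03 and -0.45 under the pericentromeric scaling. The ends of chromosome III had -0.13 on the left and -0.08 on the right. The facultative islands and meiotic genes had a median of -0.29, below each of the random lists. The euchromatic controls had 0.27, at percentile 99.68, and -0.08 with normexp. Between the settings tried the core value ranged from 2.10 to 4.11, and its direction was the same in each.

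The tiles of ade6 moved with the ectopic domain although the annotated gene lies elsewhere on chromosome III. Over positions 1317300 to 1318800, ade6 read 3.64 in wt ON, 0.61 in wt OFF, 2.36 in clr3-CDx2 ON and 4.04 in clr3-CDx2 OFF. The 20 tiles beside it changed by 0.19 in wt and 0.16 in clr3-CDx2 from ON to OFF. The input signal of ade6 was -1.15, 0.29, -0.48 and -1.36 in the same order, low on the arrays where its enrichment was high.

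**Figure D5:**
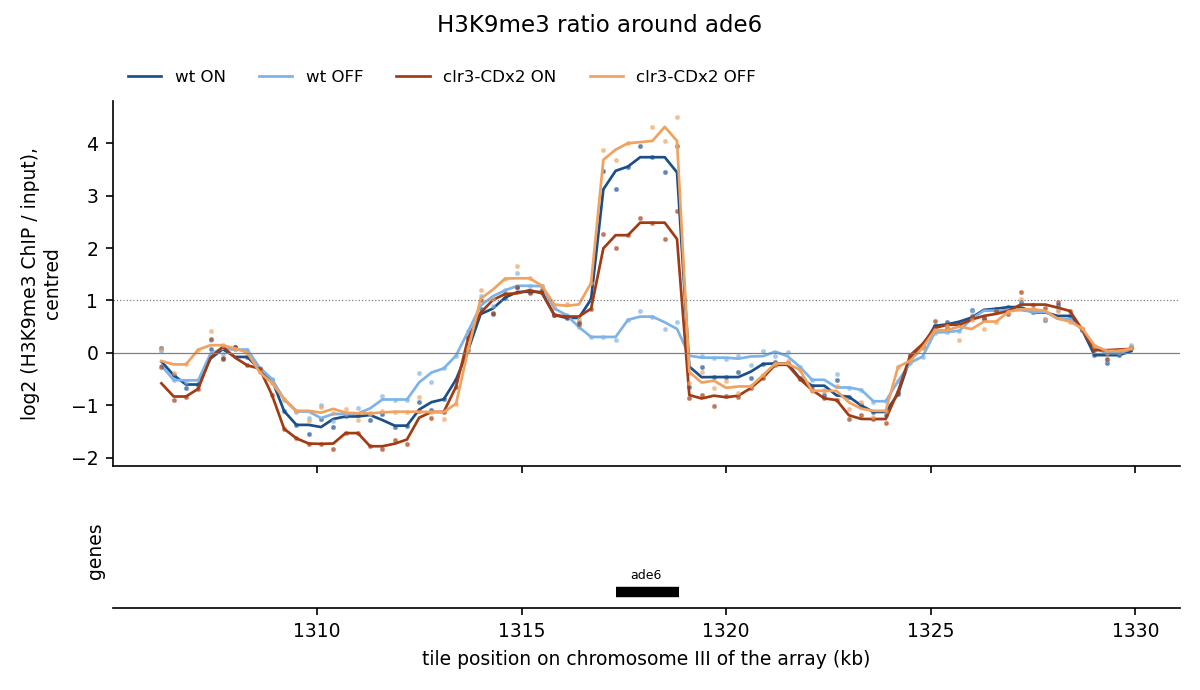
H3K9me3 enrichment (log2 ChIP over input, vertical axis) around ade6 (array position in kb, horizontal axis), with tiles as points, their running median over 3 tiles as 1 line per array and genes drawn below. Over the gene the median is 3.64 in wt ON, 0.61 in wt OFF, 2.36 in clr3-CDx2 ON and 4.04 in clr3-CDx2 OFF, while the 20 tiles beside it change by 0.19 in wt and 0.16 in clr3-CDx2 from ON to OFF.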

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

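The tests in this part were chosen after the results were seen. The ectopic core moved opposite ways after the switch in wt and clr3-CDx2, with a difference of differences of 3.69, as did its genes pmp20 (6.31), SPCC330.07c (5.94), SPCC330.03c (5.00), ura4 (4.94) and mug135 (4.38), and ade6 (4.72). These are the 6 of 4946 genes, 4945 protein-coding and the noncoding sme2, that changed by 2-fold or more in opposite directions, and 5 of them lie in the core. None of these differences was tested, since each group had 1 array, and with arrays scaled to equal pericentromeric signal the core changed by -0.55 in clr3-CDx2 as well.

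The subtelomeric clone tiles, which the comparisons do not use, carried H3K9me3 on every array. Their 129 tiles had medians of 2.58 in wt ON, 3.93 in wt OFF, 1.28 in clr3-CDx2 ON and 3.90 in clr3-CDx2 OFF.

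The tiles of ade6 moved with the ectopic domain from a distant place on chromosome III. A domain at the annotated locus is argued against by the tiles beside the gene, which changed by 0.19 in wt OFF minus ON while ade6 changed by -3.04. A change in gene copies alone would move ChIP and input the same way, but the ChIP signal of ade6 changed by -1.60 and its input by 1.46. A copy of ade6 sequence inside the ectopic domain stays open as a hypothesis: the difference of differences at ade6, 4.72, lay within the 1.94 to 6.31 of the 8 core genes analysed, but ade6 was noticed by that value, so this is no test of it, and the labels describe no reporter.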

How the results depend on the processing

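Over 14 settings, the reported one included, the ectopic core stayed lower in wt OFF than in wt ON (-3.40 to -2.14), higher in clr3-CDx2 OFF than in wt OFF (1.29 to 3.60) and positive in the difference of differences (2.10 to 4.11), whereas clr3-CDx2 OFF minus ON ranged from -0.55 to 1.12 and clr3-CDx2 minus wt in ON from -0.58 to 0.05. Of 1969 alternative values over 181 results, 1477 stayed within the spread or within 1.5 times a count, 492 moved further and 58 changed sign. The spread was that of random windows or gene lists, and for a named gene the SD of the difference over all protein-coding genes. Of these sign changes 14 were of results beyond that spread and, for gene lists, in the outer 5% of random lists, and each is given below; beyond the spread alone, tlh1 turned to -0.39 in wt, -0.70 in clr3-CDx2 and -0.31 in the difference of differences when scaled to pericentromeres. The cause was not tested except where the setting's construction gives it (fewer tiles, other edges, a shift of each ratio). Among the 19, 20, 16, 10 and 10 genes named for the comparisons from wt OFF minus ON to the difference of differences, gene means named 17, 15, 16, 9 and 10 again. Leaving out the 1 tile dim in the input channel moved none of the values past that limit, and no setting filtered on the ChIP channel, in which 1 to 3 tiles per array were dim. These 149 and 27 values could hardly move. Nor could the 4 and 9 taken on the extent in clr3-CDx2 ON, which is the core itself. All are counted in the 1477. The alternative without saturated tiles was not run because 0 tiles were saturated. ON and OFF cells of a genotype came from 1 culture, but a paired fit over both genotypes was not run. Its 1 residual degree of freedom would be the difference of differences itself and would hold no spread between replicates. Signal over background, 137 or more in each channel, did not limit the levels of most tiles; the number of arrays limits every difference.

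Of the 492 values that moved further, 94 were pericentromere medians, domain numbers, ectopic domain values or gene counts, and these follow with the 11 others that were reversed. The remaining 387 are not listed: 231 lay closer to 0, 136 further from 0 and 20 on the other side of 0, and 112 of them came from the ChIP channel alone, 107 from scaling to pericentromeres and 78 from normexp. Levels are in the order wt ON, wt OFF, clr3-CDx2 ON, clr3-CDx2 OFF. With normexp: pericentromere median, wt_OFF 2.98 and pericentromere median, clr3-CDx2_ON 2.53; domains outside the fixed regions 627, 613 and 675 in wt ON, wt OFF and clr3-CDx2 ON. The ectopic domain then gave 0.75 for clr3-CDx2 OFF minus ON, 3.60 for clr3-CDx2 minus wt, OFF and 4.08 for the difference of differences, whose euchromatic controls changed sign to -0.078. Genes higher in wt OFF minus ON were 22, and genes lower were 1 in clr3-CDx2 minus wt, OFF and 1 in the difference of differences. Without background subtraction the difference of differences of the core was 3.97. With the series matrix values, domains were 601 in wt ON and 731 in clr3-CDx2 ON, and the core gave -3.13 in wt, 0.62 in clr3-CDx2, 3.10 between genotypes in OFF and 3.58 for the difference of differences. Centring on the mode gave 202 domains in wt ON and 253 in clr3-CDx2 ON, 1.12 for the core in clr3-CDx2, 4.11 for its difference of differences, 19 genes higher in wt and 6 lower in clr3-CDx2; chromosome end III right in wt changed sign to 0.0046.

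Scaled to pericentromeres, the pericentromere medians were 2.11 in wt OFF and 2.91 in clr3-CDx2 ON, domains in clr3-CDx2 ON numbered 702, and the ectopic medians were 3.45 in clr3-CDx2 ON and 2.45 in clr3-CDx2 OFF. The core then reversed to -0.55 for clr3-CDx2 OFF minus ON and to 0.053 for clr3-CDx2 minus wt in ON, and gave 2.68 in OFF and 2.50 for the difference of differences. Also reversed were clr3-CDx2 OFF minus ON at chromosome end III right (0.24), SPAC750.07c (-0.081), SPAC186.07c (-0.087) and SPAC750.08c (-0.24), the difference of differences at subtelomere I left (-0.029) and right (-0.45), and the telomeric helicases between genotypes in ON (0.51). Gene counts became 2 higher in wt, 4 higher and 28 lower in clr3-CDx2, 34 higher and 1 lower between genotypes in ON, and 18 higher and 4 lower in the difference of differences. Without repeated tiles the pericentromere medians were 0.28, 1.23, -0.41 (reversed) and 1.06, the core's difference of differences 3.94 and that of subtelomere II right -0.036 (reversed), and genes higher were 5 in wt, 23 in clr3-CDx2, 10 in ON and 24 in OFF. On the ChIP channel alone the core gave -2.14 in wt, 0.68 in clr3-CDx2, -0.36 in ON, 2.54 in OFF and 2.95 for the difference of differences. Genes were then 3 higher in wt, 8 higher and 3 lower in clr3-CDx2, 10 higher and 0 lower in ON, and 23 higher and 1 lower in OFF, and chromosome end III right in OFF changed sign to 0.0010.

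Domain edges at 1.5-fold gave 777, 745, 819 and 844 domains and ectopic medians of 2.63 in wt ON, 1.64 in clr3-CDx2 ON and 1.59 in clr3-CDx2 OFF, with differences of -2.27 in wt, 0.16 in clr3-CDx2, 1.29 in OFF and 2.10 for the difference of differences. Edges at 3-fold gave 57, 80, 75 and 117 domains, 0.50 for the core in clr3-CDx2 and 3.11 in OFF, and runs of at least 10 tiles gave 143, 160, 176 and 195 domains. The domain over its wt ON extent had medians of 2.63, 1.64 and 1.69 in wt ON, clr3-CDx2 ON and clr3-CDx2 OFF. Its differences were -2.29 in wt, 0.16 in clr3-CDx2, 1.29 in OFF and 2.10 for the difference of differences. The extent in clr3-CDx2 ON is the core itself, so its 13 values could not move and are no check on the choice. Keeping marked tiles, chosen after seeing the data, gave pericentromere medians of 3.56, 4.50, 2.76 and 4.36 and 3.94 for the core's difference of differences.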

Other observations

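The tests in this part were chosen after the results were seen, as were the genes of its opening paragraph. A set of 6 genes known to be repressed by thiamine, taken by hand after nmt1 and bsu1 had been seen to rise, gained signal in OFF cells, to which thiamine had been added, and the set does not stand for thiamine-repressed genes at large. These 6, nmt1, thi2, thi4, thi9, bsu1 and pho4, were at least 2-fold higher in OFF in both genotypes, with median differences of 2.02 in wt and 2.75 in clr3-CDx2. Their median level went from -1.57 to 0.08 in wt and from -1.91 to 0.26 in clr3-CDx2, so that in OFF cells they stood near the median tile rather than above it. nmt1 went from -2.21 to 0.06 in wt and from -2.65 to 0.25 in clr3-CDx2, and bsu1 alone of the 6 passed 2-fold enrichment, at 1.26 in wt OFF and 1.40 in clr3-CDx2 OFF.

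Small domains outside the fixed regions came and went with the switch in both genotypes. There were 7 present in ON and absent in OFF in both, of which 2 moved by 2-fold or more: 2.10 kb at coq6 and myo1 (-2.06 in wt, -2.16 in clr3-CDx2) and 2.40 kb at SPAP32A8.02 and bop1 (-1.34 and -1.74). There were 24 present in OFF alone in both, of which 3 moved as far: bsu1 (2.67 and 2.92), SPAC57A7.05 (1.87 and 2.72) and SPCC162.02c (1.99 and 2.43). The left end of chromosome III read 0.79 in wt ON, 0.16 in wt OFF, -0.86 in clr3-CDx2 ON and -1.62 in clr3-CDx2 OFF. The 61 tiles of the mitochondrial genome, DNA without histones, read -2.95, -2.74, -3.14 and -2.49 in the same order. The 11 construct and marker loci, among them leu1, his3 and lys1, had median differences of 0.19 in wt OFF minus ON, 0.27 in clr3-CDx2 OFF minus ON, -0.23 between genotypes in ON and 0.09 in OFF.

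Input signal mostly moved against enrichment over the fixed regions and the ectopic core, although the levels did not follow this everywhere: the 10 measured Tf2 elements, on repeated tiles, read 1.86 to 2.56 with input of 0.49 to 1.38, and the left end of chromosome III read 0.79 in wt ON with input of 0.995. Input differences alone would leave the ChIP channel unchanged, but in wt OFF minus ON the ChIP signal of the core changed by -2.14 while its input changed by 0.76. Copy number would move both channels the same way, and they moved opposite ways in 39 of 44 pairs of region and comparison, 31 of them with both channels in the outer 5% of random windows, of which 44.6 to 59.8% had opposite signs (the pairs share 4 arrays and are not independent), but it stays open at the right end of chromosome III in wt OFF minus ON, the 1 pair with both channels in the outer 5% in the same direction (ChIP -0.36, input -0.20). In clr3-CDx2 OFF minus ON the channels of that end did not move alike, with ChIP at -0.04 and input at 0.21. Less DNA recovered from heterochromatin in the whole-cell extract stays open as a hypothesis: it was not excluded by the 40 pairs outside the ectopic domain, 35 of them in opposite directions, but it was found from these pairs, so they do not support it. Competition of the labelled samples for a spot could give the same pattern and stays open in the same way.

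Subtelomere I right was higher in clr3-CDx2 than in wt both before and after the switch. A scaling of the whole array would raise other heterochromatin too, but the pericentromeres differed by -0.78 in ON. Repeated sequence shared between chromosome ends is argued against by tiles on unique sequence, which were 2.27 higher in ON and 3.14 higher in OFF. A strain difference apart from clr3, for example at this chromosome end, cannot be told apart from an effect of clr3-CDx2 with 1 strain per genotype, and the other ends gave no single answer: subtelomere II left differed by 0.033 in ON and 0.33 in OFF (-0.04 and 0.25 on its unique tiles, 0.64 and 1.49 on its repeated ones), subtelomere I left by 0.12 and 0.69 (0.74 and 0.98 on its unique tiles, 0.02 and 0.58 on its repeated ones), subtelomere II right by -0.18 and -0.20 (-0.27 and -0.39 on its unique tiles, 0.47 and 1.31 on its repeated ones) and the ends of chromosome III by -1.63 and -1.78 on the left and -0.32 and -0.47 on the right. All 59 tiles of the left end of chromosome III are repeated, so it has no unique tiles to compare. An effect of clr3-CDx2 itself may be at work and was not tested.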
